A study of Mus musculus with 2 samples.

How the data were processed

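Chromatin immunoprecipitation sequencing (ChIP-seq) was used to map NELF-B in mouse embryonic fibroblasts. Per the labels, the cells came from an embryo with 1 floxed and 1 null Nelf-b allele, on a mixed genetic background, and were growing asynchronously in medium with 10% serum. Fixation took 15 min in formaldehyde at 1%, and shearing gave pieces of 300 to 500 bp, per the labels' protocols. NELF-B was precipitated with a purified polyclonal antibody. Library fragments of 175 to 225 bp were selected on a gel and amplified for 18 cycles, per the labels' protocols. The series holds 1 NELF-B library and 1 input library. The input library has no file of its own in the data used here. There are no replicates, so no value has a replicate error.

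The deposited file holds 3 tracks with 9095 entries each, per the file headers: summits with a number, intervals, and active regions. The intervals of the last 2 tracks were identical in all 9095 entries, and each of the 9095 summits lay inside the interval of the same order. The number beside each summit is a score given by the authors, called summit height below. All 9095 heights were whole numbers. Neither the file headers nor the labels say what the height counts, so the unit is the authors' own and heights were compared only within this list. The submitters' processing notes name MACS, a peak caller, without a version. The aligner, the threshold, the use of the input library as a control and the genome build are not given in the sources used here. Sequencing depth is therefore unknown, and no interval or floor that needs it is given. In the deposited file, 9005 of the 9095 summit positions were multiples of 16 bp, which limits their resolution. Region starts were raised by 1 so that positions count from 1, and summits are printed as deposited.

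The gene table used here is of assembly GRCm38.p6. A total of 88 regions on 7 chromosomes started past the last gene of their chromosome in that table, and on chromosome 7 the list went 7.19 Mb past it. The list is therefore in other coordinates than that assembly. No region was assigned to a gene, and the planned comparisons at transcription start sites, of 34 gene lists and of sequence content were not made. From the table only the number of genes on each chromosome was used, and for 1 gene list (replication-dependent histones) its chromosomes and which genes neighbour each other. Of the 44 genes of that list, 44 were found. Genes were 20168 protein-coding genes on chromosomes 1 to 19 and X, after 1463 olfactory and vomeronasal receptor genes were left out by their symbols.

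Computation used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Chromosome length was taken as the end of the last region. Region numbers have exact Poisson 95% intervals and shares have exact Clopper-Pearson 95% intervals. Both cover counting error over regions of 1 library only and treat regions as independent. Ratios of heights and the rank correlation have percentile intervals from 1000 bootstrap resamples of regions, which treat regions as independent. For distances, regions of the same widths were placed at random 1000 times on the same chromosome, without overlap, between its first and last region. A further 1000 placements moved each region to a random position within 1 Mb of its own. These first allowed overlaps, and after their result was seen they were changed to draw overlapping regions again. Both versions are given. The distribution of gaps used 100 placements of each kind. Runs of tall regions were scanned with a running median over 25 consecutive regions, beside 200 shuffles of the heights within each chromosome. The number of tall regions in clumps was set beside 1000 random draws of as many regions from each chromosome, a comparison added after the clumps were seen. No p-values are given, since regions of 1 library are not replicates. On simulated layouts of 9095 regions the neighbour count was checked: with no planted pairs it found 7.92% of regions with a neighbour where 7.58% were expected, and with 30% of regions planted in pairs it found 34.4% where 35.3% were expected. The pairs were planted within the counted distance, so this checks the counting and not whether clustering can be told from uneven density.

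The main settings, the gene lists and the alternatives were fixed before the data were examined, except those on genes per chromosome, empty windows, heights beside neighbours, runs of tall regions, heights on chromosome 8, density between the first and last region of a chromosome, and the redrawing of overlapping placements, which were chosen after seeing the data. Named regions followed a fixed rule: the 10 with the highest summit, the 5 widest, and the 5 windows of 1 Mb with the most regions. Of the tests of explanations written before their results were seen, 4 on the densest windows and on neighbours were set aside when the tall clumps and chromosome 8 were taken up instead, and their values are given in the closing section. The longest empty stretches, the clumps of tall regions and the tallest regions of X were named after their values were seen.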

Results

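NELF-B is a subunit of the negative elongation factor, a complex that holds RNA polymerase II shortly after it starts transcription. The file's track headers call it Cobra1, an older name of the gene Nelfb. The series asked where NELF-B binds on the chromosomes of mouse embryonic fibroblasts, primary connective tissue cells cultured from an embryo. The data are 1 list of enriched regions from 1 NELF-B library. The input library contributed no values, and its use in making the list is not stated. Sequencing depth is unknown. Each region has a start, an end, a summit position and a summit height in the authors' own unit. The genome build is not given in the sources used here, so positions are those of the file and no gene is assigned to a region.

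NELF-B was enriched at 9095 regions, found on all 19 autosomes and on X. The list had 0 regions on Y and 0 on the mitochondrial genome. Together the regions covered 11.0 Mb. They were narrow, with a median width of 1138 bp and quartiles of 956 and 1383 bp. The median summit height was 44, with quartiles of 32 and 65, and heights ran from 12 to 730. The 909 tallest regions, the top 10% of the list, held 26.4% of the summed height, and 117 regions rose above 200. Summits lay near the middle of their regions, at a median of 48.6% of the width, with quartiles of 38.8% and 58.3%.

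The 10 tallest regions lay on 7 chromosomes. The tallest was on chromosome 3 from 96071975 to 96074376, with a height of 730, which is 16.6 times the median. A neighbour 3.44 kb away, at 96065565 to 96068531, reached 556. Chromosome 13 also held 2 of the 10. The region from 21870575 to 21872948 reached 576, and the region from 23672866 to 23674837 reached 531. On chromosome 11, heights of 575 at 69571179 to 69573496 and 503 at 115885067 to 115886631 were found. Single regions of this rank lay on chromosome 8 at 11557372 to 11559009 (height 593), on chromosome 17 at 24664104 to 24666651 (556), on chromosome 9 at 88417018 to 88418567 (508) and on chromosome 15 at 79912983 to 79914907 (508). Each of these 10 regions was wider than the median region, by 1.36 to 2.61 times. With 1 library, the order of these heights has no replicate check.

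Taller regions were wider. The median width rose from 926 bp in the lowest 10% of heights, with quartiles of 785 and 1100 bp, to 1364 bp in the highest 10%, with quartiles of 1157 and 1691 bp. Across the 9095 regions, Spearman's rho between height and width was 0.42 (bootstrap 95% interval 0.40 to 0.43). The widest region spanned 6113 bp on chromosome 17 from 39979801 to 39985913, or 5.37 times the median width. Its height was 253, its summit lay at 39980256, close to its left edge, and the nearest other region was 1031 kb away. No filter for repeated sequence was applied here and no input values were at hand, so this region may reflect background rather than NELF-B. The other 4 of the widest regions spanned 3491 to 3768 bp, with heights of 145 to 184, on chromosomes 5, 10, 11 and 12. Regions of 1 list are not replicates, so the correlation describes this list.

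**Figure D1:**
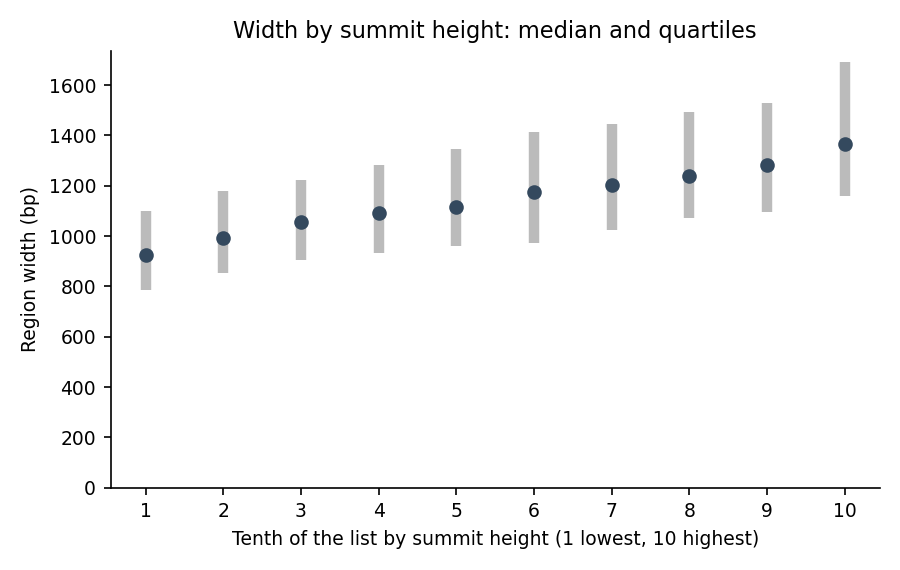
Region width in bp (y axis) against the tenth of the list by summit height (x axis, 1 lowest, 10 highest). Points are medians and bars run from the lower to the upper quartile of about 910 regions each; the median rises from 926 to 1364 bp.

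Chromosomes differed in how many regions they held. Chromosome 11 had the most, with 743 regions or 6.10 per Mb (exact Poisson 95% interval 5.67 to 6.56). It was followed in density by chromosome 17 at 5.24 per Mb (4.79 to 5.72) and chromosome 19 at 5.06 per Mb (4.51 to 5.65). Among autosomes, chromosome 1 was the sparsest at 2.19 per Mb (1.99 to 2.40). The median over the autosomes was 3.67 per Mb. Chromosome X held 210 regions, or 1.26 per Mb (1.10 to 1.44), below each of the 19 autosomes. Its density was 0.344 of the autosomal median (0.299 to 0.394), and 0.218 of it when only the taller 50% of regions were counted.

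The number of regions followed the number of protein-coding genes on a chromosome more closely than its length. Across the 20 chromosomes, Spearman's rho with the gene number was 0.89 and Pearson's r was 0.89. Without chromosomes 7 and 11, the 2 farthest from the median gene number, both were 0.85. With chromosome length, rho was 0.42 and r was 0.39. Both values for length include X, with 210 regions over 166 Mb, and neither was computed without it. Chromosomes of 1 library are not independent samples, so no p-value is given, and the gene numbers come from assembly GRCm38.p6. On autosomes there were 46.3 regions per 100 protein-coding genes. Single autosomes ranged from 36.6 on chromosome 1 (exact Poisson 95% interval 33.3 to 40.3) to 53.1 on chromosome 8 (48.7 to 57.7). Chromosome X had 21.9 per 100 genes (19.0 to 25.1), and its interval lay below the lowest autosome. Leaving out X raised rho with the gene number to 0.93.

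Heights also differed between chromosomes. Chromosome 8 had the highest median, 52, or 1.18 times that of the other autosomes (bootstrap 95% interval 1.11 to 1.25). Chromosome 17 followed with a median of 51 (ratio 1.16, 1.11 to 1.25). Of the regions on chromosome 8, 18.1% were among the tallest 10% of the list (exact 95% interval 15.0 to 21.6). This share was 16.7% on chromosome 6 (13.5 to 20.3) and 15.1% on chromosome 11 (12.6 to 17.9). On chromosome 12 it was 5.54% (3.20 to 8.84). Chromosome X had the lowest median height, 37, at 0.841 of the autosomal median (0.778 to 0.886), and 3.81% of its regions were among the tallest 10% (1.66 to 7.37). Its tallest region, at 12857031 to 12858550, reached 272.

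**Figure D2:**
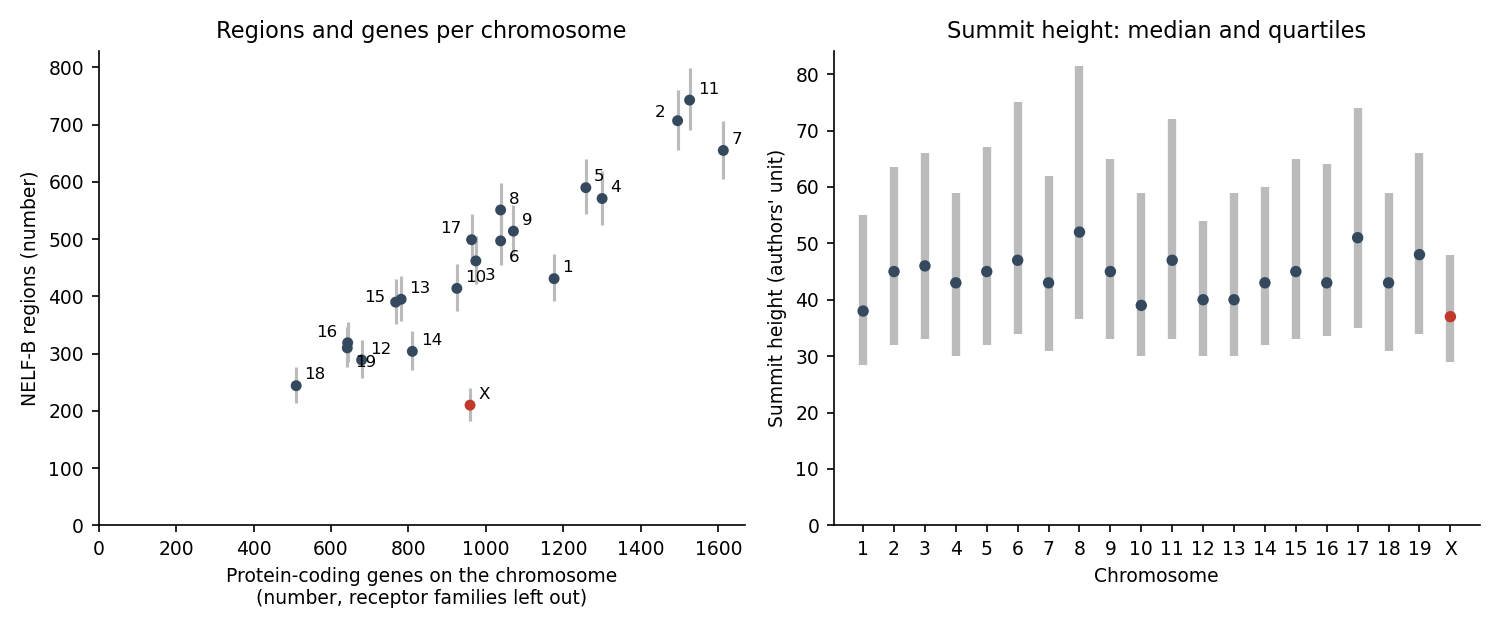
Left, number of NELF-B regions (y axis, with exact Poisson 95% intervals) against the number of protein-coding genes (x axis) for each chromosome, named beside its point. Right, summit height in the authors' unit for each chromosome, with points for medians and bars from the lower to the upper quartile; X (red) has 210 regions for 959 genes and a median height of 37, and chromosome 8 has the highest median, 52.

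NELF-B regions lay closer together than random placement gives. Of the 9095 regions, 1562 or 17.2% had another region within 10 kb (exact 95% interval 16.4 to 18.0). That interval treats regions as independent, though each neighbour has a neighbour in turn, so it may be too narrow. Regions placed at random on the same chromosomes gave 7.52% ± 0.38 (SD over 1000 placements), with a highest value of 8.75%, so the observed share was 2.28 times as large. Placements within 1 Mb of each region gave 13.7% ± 0.48, with a highest value of 15.4%. They keep the density over megabases only in part, leaving 604 windows of 1 Mb empty on average where 803 were found empty. The excess over these was 1.25 times, and 1.10 times when the moved regions were allowed to overlap, where the highest placement reached 17.1%. Below 10 kb, only gaps of 5 to 10 kb exceeded the placements without overlap within 1 Mb, with 577 found and 276 to 371 placed. The 225 gaps of 2 to 5 kb lay within their range of 162 to 238. The excess went on in longer gaps, with 896 found and 522 to 652 placed at 10 to 20 kb, and 1918 found and 1351 to 1516 placed at 20 to 50 kb. Gaps under 1 kb were rare, with 9 found and 49 to 95 in those placements. The regions with a neighbour within 10 kb had a median height of 46, against 44 for the rest (bootstrap 95% interval of the ratio 1.02 to 1.09).

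**Figure D3:**
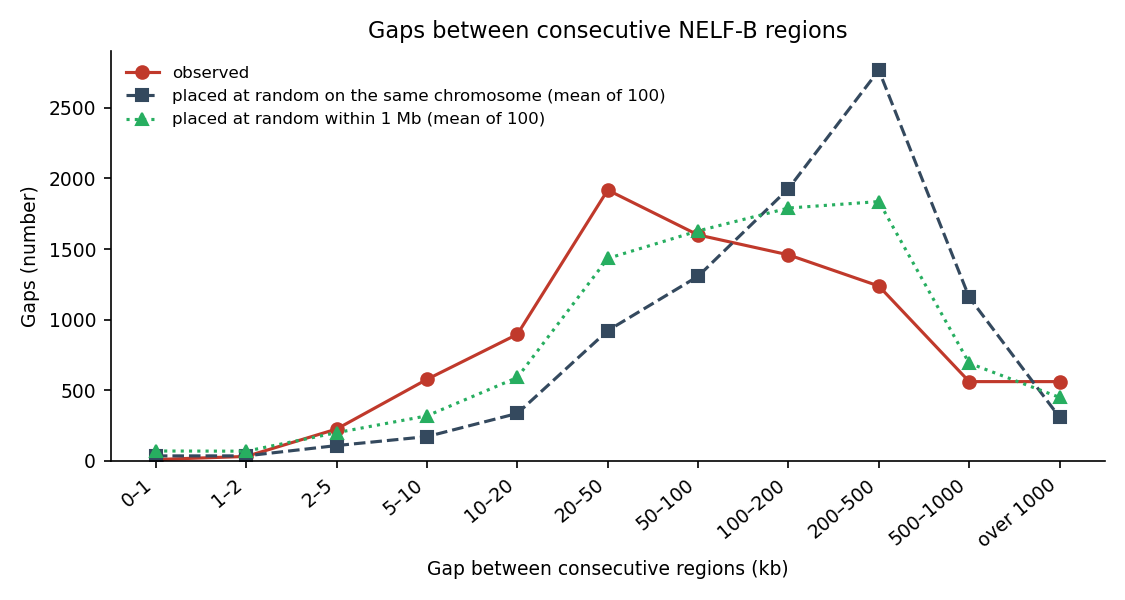
Number of gaps between consecutive regions (y axis) by gap length in kb (x axis, unequal bins). Red circles are observed, dark squares are the mean of 100 random placements on the same chromosome, and green triangles are the mean of 100 placements within 1 Mb of each region; at 5 to 10 kb, 577 gaps were observed, above both kinds of placement.

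At the scale of 1 Mb, regions were concentrated in part of the genome. Of 2531 windows of 1 Mb, 803 or 31.7% held no region (exact 95% interval 29.9 to 33.6). Random placement on the chromosome left 126 windows empty on average and 160 at most, and placements within 1 Mb of each region left 604 on average, so the excess fell from 6.39 to 1.33 times. The densest window was on chromosome 7 from 52000001 to 53000000, with 36 regions, where random placement on the chromosome never exceeded 22 in any window but placements within 1 Mb reached 40. Next were chromosome 19 from 5000001 to 6000000 with 34 regions and chromosome 7 from 134000001 to 135000000 with 32. Chromosome 15 from 76000001 to 77000000 held 29, and chromosome 10 from 80000001 to 81000000 held 28. In all, 21 windows held more than 22 regions, with 6.14% of the list between them, and 4 of these windows were on chromosome 17. Heights in the 5 densest windows were ordinary, with medians of 41 to 48, and none of the 10 tallest regions lay in them. The longest stretches without a region were 15984 kb on X from 110299416 to 126283853 and 12971 kb on X from 54646849 to 67618144. Assembly gaps and unmappable sequence were not excluded, so part of the empty windows can be sequence that no read could reach.

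The tallest regions lay near each other more often than random draws from the list. Of the 90 tallest regions, the top 1% with heights of at least 228, 43 lay in 14 clumps of 2 or more members at most 1 Mb apart. Random draws of as many regions from each chromosome put 18.1 ± 4.89 (SD over 1000 draws) in such clumps, and 36 at most. Some clumps also held ordinary regions: on chromosome 11, from 115375282 to 116715692, 3 of the 90 lay among 32 regions with a median height of 49.5. The largest clump spanned 235 kb on chromosome 13, from 23621649 to 23856683, and held 11 of the 90. All 13 regions of the list inside it had heights of 207 to 531, with a median of 365, and their median width was 2437 bp. A second clump on chromosome 13, from 21844446 to 21872948, held 2 regions with heights of 265 and 576. On chromosome 3, from 96023060 to 96362701, 4 of the 90 lay among 12 regions whose heights ran from 20 to 730. On chromosome 11, 4 lay between 87235540 and 87277253. Chromosome 11 held the most of the tallest 1%, 17.8% against 8.17% of all regions, followed by chromosome 13 with 14.4% against 4.34% and chromosome 17 with 11.1% against 5.49%. The highest running median over 25 consecutive regions was 218, on chromosome 13, where 200 shuffles of the heights within chromosomes reached 103 at most. The other 19 chromosomes had highest running medians of 47 to 84, below that maximum. Over 51 consecutive regions the highest was 66, on chromosome 8.

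**Figure D4:**
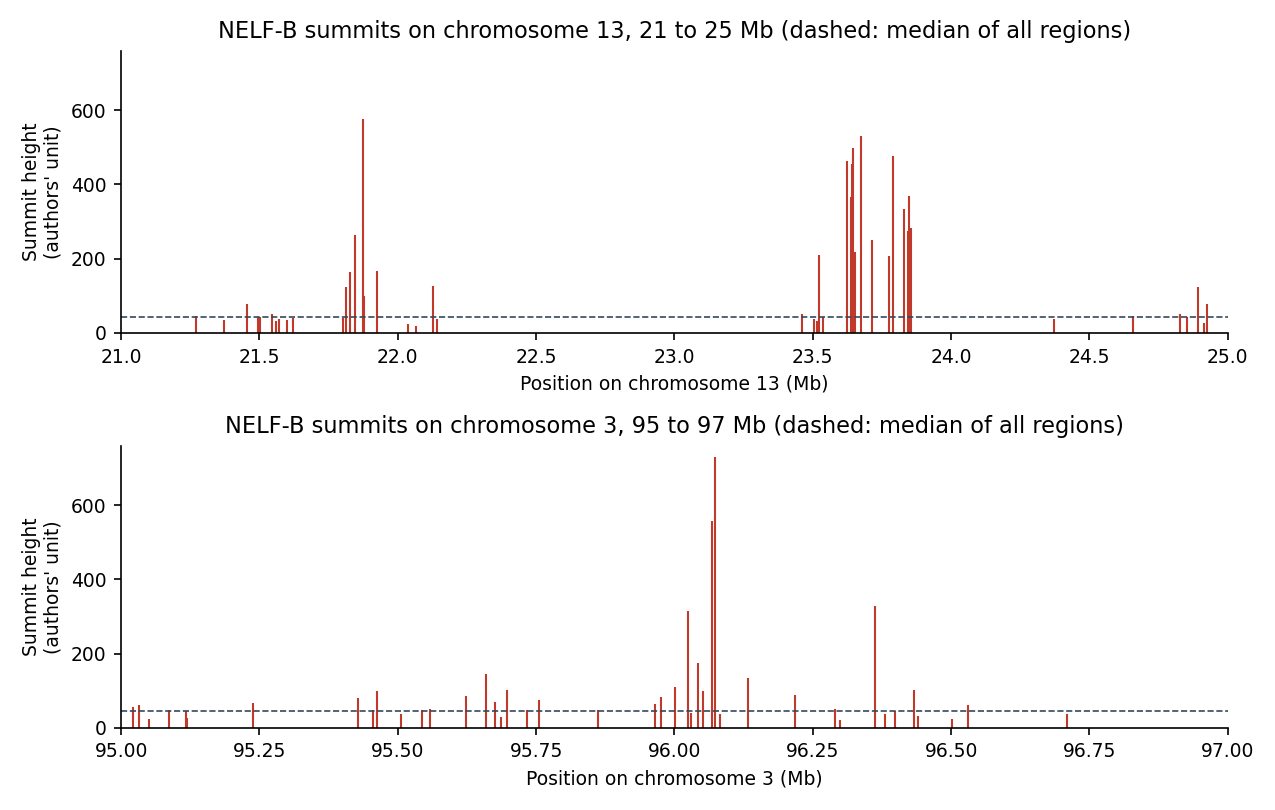
Summit height in the authors' unit (y axis) at the position of each summit in Mb (x axis) on 2 stretches, of chromosome 13 (upper) and chromosome 3 (lower). Each line is 1 region and the dashed line is the median of all regions, 44; the clump from 23621649 to 23856683 on chromosome 13 has heights of 207 to 531.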

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

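The alternatives on genes per chromosome, empty windows, neighbour heights, runs, chromosome 8, and density between the first and last region were chosen after the results were seen, as was the redrawing of overlapping placements within 1 Mb. Of 72 alternatives over 9 results, 56 left the value inside its interval or its count within 1.5 times, 16 moved it, and none turned a direction. For each of 2 correlations, 20 of these alternatives left out 1 chromosome in turn, and none of those moved the value. Leaving out X and using autosomes only are the same setting there and were counted separately. The tally is therefore weighted towards unchanged values. The list shrank to 4547 regions for the taller 50% and to 909 for the tallest 10%, by construction. The density of X over the autosomal median fell to 0.218 for the taller 50%. The correlation of height and width was 0.38 without the widest 5% of regions, and 0.41 to 0.42 when each chromosome was left out in turn. The ratio of neighbours within 10 kb to random placement was 2.94 for the taller 50%, 1.86 for neighbours within 50 kb 1.25 for placements within 1 Mb of each region and 1.10 for these as first made, with overlaps. The correlation of regions with genes was 0.42 when length replaced the gene number, and 0.87 to 0.93 when each chromosome was left out. For the taller 50% it was 0.79, inside the wide interval of the main value, 0.69 to 0.97. Empty windows over random placement fell from 6.39 to 2.42 for windows of 500 kb, 2.23 for the taller 50% and 1.33 for placements within 1 Mb. Regions with a neighbour within 50 kb were 1.10 times as tall as the rest. The highest running median was 66 over 51 regions, then on chromosome 8. The ratio of median heights on chromosome 8 was 1.27 for the first 50% of its regions and 1.09 for the last 50%. Apart from the first 2, the cause was not tested. No replicate could be left out, no paired analysis was possible because the series has 1 library per group, and alternatives on transcription start sites, gene lists and sequence were not run because the list is not in the coordinates of the gene table. The unknown depth limits every height.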

Other observations

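The tests in this part were chosen after the results were seen, except the ratio of median heights on X, the number of regions per gene on X and the 4 tests of the next paragraph.

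The 4 tests written beforehand on the densest windows and on close neighbours were run and then set aside for the clumps and chromosome 8. In the 5 densest windows 22.0% of regions (exact 95% interval 15.8 to 29.3) had heights at or below the lower quartile of the list, where extra copies were to leave under 5%. The lower quartile of the gaps there was 10542 bp, far above the 1000 bp bound set against a broad area cut into pieces. Of the gaps under 10 kb, 1.07% (0.490 to 2.02) were under 1 kb, below the 15% bound set against areas split by the caller. How the caller joins close pieces is not known here, and joining would leave few short gaps either way. Neither gap test can therefore exclude splitting. For uneven density over megabases, the test as first made, with overlapping placements within 1 Mb, did not reach its bound: the share with a neighbour was 17.2% (16.4 to 18.0), and these placements gave 15.7% on average and 17.1% at most. The version without overlaps, made after that result was seen, had a maximum (15.4%) below the interval. The gap lengths were compared later: 577 gaps of 5 to 10 kb were found, against 270 to 346 with overlaps and 276 to 371 without. Only 9 gaps were under 1 kb, against 171 to 242 with overlaps and 49 to 95 without. The placements set no smallest gap between regions, so the excess at 5 to 10 kb does not decide against uneven density. Moves of up to 1 Mb also even out density (604 empty windows on average, 803 found), so unevenness on a smaller scale stays open.

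Heights of consecutive regions were correlated most at the shortest distance, weakly up to 200 kb, and not measurably beyond. For the 40 pairs of consecutive regions less than 2 kb apart, Spearman's rho between the heights was 0.64 (bootstrap 95% interval 0.41 to 0.80). It was 0.21 (0.14 to 0.27) for 802 pairs 2 to 10 kb apart, 0.09 (0.05 to 0.13) for 2814 pairs 10 to 50 kb apart, 0.11 (0.07 to 0.14) for 3059 pairs 50 to 200 kb apart, and 0.02 (-0.01 to 0.07) for 2360 pairs over 200 kb apart. Chromosome 11 held a clump of 5 regions from 87235540 to 87277253 with heights of 184 to 328, and 3 regions from 101503227 to 101522084 with heights of 235 to 246.

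Replication-dependent histone genes were first set against the densest windows, and that test went against them, since 5 of the 5 densest windows lie on chromosomes with none of the listed genes (clusters of replication-dependent histone genes, densest windows). They were then taken up as a candidate explanation for the tall clumps of chromosomes 13 and 3, because the gene table puts 39 of the 44 on chromosome 13 and 5 on chromosome 3, which ranked 1 and 3 of 20 by highest running median (clusters of replication-dependent histone genes, by chromosome). Chromosome 11, with none of them, ranked between these, and the 83 of chromosome 3 lay below the shuffle maximum of 103. On chromosomes with none lie 10 of the 14 clumps, with 24 of the 43 regions, so these genes cannot account for those 10. Random draws over all chromosomes also put 18.1 ± 4.89 regions in clumps, and no comparison without chromosomes 13 and 3 was made. Whether those 10 clumps exceed what random draws give is therefore not known, and they decide nothing about chromosomes 13 and 3. The order of genes leaves it open: on chromosome 13 the listed genes form 3 groups, of 7, 4 and 28 (clusters of replication-dependent histone genes, by neighbours). A group was ended by 10 other genes, and 11 lie between the 7 and the 4, so the number of groups rests on that setting. Between the 4 and the 28 lie 41 other genes, 35 of them receptor genes. The tallest 1% of regions forms 2 clumps there, with 11 regions and a stretch of 1.32 Mb without any between them. The lower quartile of the gaps inside the largest clump was 4889 bp, above the 1000 bp bound set against 1 broad area cut into pieces. How the caller joins close pieces is not known here, so this speaks only against cuts at short gaps. For the view that extra copies of the stretch raise every region in it, 0 of the 13 regions lay at or below the median height. The clump was picked for its tall regions, so that test decides nothing.

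The low number of regions on X is not explained by its gene number, since X had 21.9 regions per 100 genes where the lowest autosome had 36.6. The ratio of median heights, 0.841 (0.778 to 0.886), argues against a single copy of X that lowers the heights, since its lower bound lay above the 0.75 set beforehand. That bound took no account of a threshold that removes the lowest regions. Among the floors tried, from 12 to 32, only 25 let halved heights match both number and median, so the match rests on 1 tuned value. The 11.0% of X regions and 8.95% of autosomal regions below 25 speak against a sharp floor, not against halving. A later test, higher up the range, found 49 X regions of height 50 or more, 1.33 times (0.985 to 1.76) the 36.8 that halved autosomal heights would give, while the 27 at 60 or more (17.8 to 39.3) included the 21.9 for halving and the 88 at 40 or more (70.6 to 108) missed the 68.7. Halving with a gradual loss of low regions may remain, as may a smaller share of active genes on X, which was not tested, and the sex of the embryo is not in the labels used here.

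Heights on chromosome 8 were greater over the whole distribution, with ratios to the other autosomes of 1.14 at the lower quartile (1.09 to 1.22), 1.18 at the median and 1.27 at the upper quartile (1.17 to 1.34). Such a shift was not particular to chromosome 8. Chromosome 17 had ratios of 1.09 (1.00 to 1.19), 1.16 (1.11 to 1.25) and 1.16 (1.09 to 1.23), and chromosome 1 lay lower, with 0.891, 0.844 and 0.846. A few tall stretches do not account for all of it: of 10 contiguous blocks of its regions, 10 had a median above that of the other autosomes, and without the 3 highest blocks the ratio of medians was still 1.14 (1.07 to 1.20). Extra copies of the chromosome in part of the cultured cells may raise all heights in this way, but chromosome 8 was picked for its heights, and the first 50% of its regions gave 1.27 where the last 50% gave 1.09. The kind of genes on the chromosome was not tested, and the design names no biological difference that bears on it. An input signal per chromosome, which would decide, was not analysed here.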
